A study of Caenorhabditis elegans with 6 samples.

How the data were processed

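RNA from whole Caenorhabditis elegans was measured on 6 single-colour Affymetrix arrays, 1 for each combination of 3 strains and 2 treatments. The strains were the wild type N2, a daf-16(mu86) mutant and a ser-3(ok2007);ser-6(tm2146) double mutant, called the receptor mutant here. Per the labels, animals grew for 3 days and were then kept for 2 days on plates without or with octopamine at 20 mg/mL, and total RNA was extracted with TRIzol and labelled with biotin. The deposited values are linear intensity values, 1 per probe set and array. The method the authors used to summarise probes and normalise arrays is not given in the sources used here, nor is the genome build behind the array design.

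The deposited table held 22625 probe sets. The 77 control probe sets were left out of the gene comparisons, which left 22548. A platform annotation listed 21653 of these probe sets: 20766 had 1 gene, 887 had several genes and were not assigned to a gene, and 895 of the probe sets used were unnamed. Entrez identifiers matched 20701 probe sets to the current gene table of assembly WBcel235, and 0 symbols changed. That table served only for names and for the order of genes along chromosomes. The named probe sets covered 17118 genes. For a gene with several probe sets, the one with the highest mean over the 6 arrays was used. Among the genes analysed, 2163 had several probe sets, and 3595 of the probe sets used carried a suffix (_x or _s) that marks probes matching more than 1 transcript.

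Intensities were converted to log2 with no pseudocount. The array medians as deposited spanned 0.13 on the log2 scale, above the tolerance of 0.1 that had been set, so each array's median was subtracted. Genes were kept when their mean over the 6 arrays reached the 40th percentile of all probe sets, a signal of 15.5, which left 10251 genes. Median signals as deposited were 23.8 and 25.3 in N2 without and with octopamine, 24.6 and 25.2 in daf-16, and 25.1 and 26.0 in the receptor mutant. Between 52.5% and 53.5% of probe sets had a signal under 30 on each array. With 1 array per group, the number of arrays limits the precision, and no comparison between a pair of arrays has a replicate check or a p-value. Such comparisons are given as log2 ratios and as counts of genes at or past 2-fold.

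A test was available only from all 6 arrays together. An additive model in limma 3.58.1 (R 4.3.3) had terms for strain and octopamine, with a mean-variance trend in the empirical Bayes step and Benjamini-Hochberg adjustment over the 10251 genes at a threshold of 0.05. It treats the 3 strains as 3 pairs of arrays, with 2 residual degrees of freedom and 6.28 prior degrees of freedom. The spread of the octopamine change between strains is its error, so a change specific to 1 strain counts as error. The same model tests each mutant against N2 over both treatments. The labels do not say that the arrays came from separate cultures, so its p-values measure only the spread between these arrays. The words rose and fell are used only for genes past this threshold.

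For each of 50 gene lists the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list is said to stand apart when its median lies outside the central 95% of the random medians, as a description of these arrays. Gene-list counts from the additive model are given over all genes and adjusted over the list alone. For comparison, of all 10251 genes 755 rose and 1511 fell with octopamine, against 972 and 877 after quantile normalization. An excess of falling genes in a list thus depends partly on scaling. Correlations are across genes, which are not independent replicates. Where a pair of comparisons shares an array, the correlation and covariance of simulated comparisons without effects stand beside the observed ones. Shares carry 95% Wilson intervals, which treat genes as independent and so do not measure the spread between arrays or animals.

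The additive model was tested on simulated data for octopamine across the 3 strains, with 10251 genes of which 200 were changed in each of 5 rounds. It recovered 74.3% of genes changed by 0.5 on the log2 scale, and 100% of those changed by 1 or by 2, and 6.54% of its calls fell on unchanged genes. The list procedure was tested on the ratios of octopamine in N2 shuffled across genes, with random lists of 20 genes. Of these, 0 of 20 unshifted lists and 20 of 20 lists shifted by 0.3 stood apart. Shuffling removes shared regulation of list members, so the test does not show how often a list of co-regulated genes stands apart. Calculations other than the model used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

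The gene lists, comparisons, alternatives and the rule for named genes were fixed before the data were examined. The rule took the genes with the highest and lowest ratios in each comparison (with locus names preferred), the genes whose octopamine change differed most between N2 and each mutant, the genes past 2-fold the same way in all 3 strains, the genes with the smallest p of the additive model, up to 4 members per gene list and comparison, and daf-16, ser-3, ser-6, sod-3, mtl-1, hsp-12.6, gst-4, acs-2, tbh-1 and tdc-1. Other list members are named as examples only. Alternatives were no filter on dim genes, a filter at the 60th percentile, quantile normalization, values as deposited, a threshold of 1.5-fold, the mean of a gene's probe sets, and a floor at the 20th percentile. For the additive model they also included no trend, no strain term and leaving out each strain's pair of arrays. Leaving out probe sets with the suffixes above was added after seeing the data.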

Results

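Transcript levels were measured in whole adult C. elegans of 3 strains, each without and with octopamine, the invertebrate counterpart of noradrenaline. The question, from the title of the series, was how octopamine relates to stress resistance and to the fasting-responsive FOXO transcription factor DAF-16. The daf-16 strain lacks that factor, and the receptor mutant lacks the octopamine receptors SER-3 and SER-6. Each of the 6 groups was 1 array, so differences between a pair of arrays carry no replicate check. Correlations between arrays over genes ranged from 0.963 to 0.994. Changes of genes with a signal below the 15.5 of the filter on any array are uncertain in size. Among genes named below these are ilys-2, lys-3, lys-10, fmo-2, nspe-7, clec-190, clec-223, spe-6, cpt-4, sod-3, spp-12, nlp-35, dyf-3, lrk-1, haf-6, haao-1, bcf-1 and F15B9.6.

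The targeted genes were read first. A probe set of daf-16 was lower in the daf-16 strain by log2 ratios of -2.76 without and -2.78 with octopamine, and another by -1.45 and -1.58. The remaining pair of daf-16 probe sets differed less, at -0.48 and -0.54 for the one and -0.37 and -0.45 for the other. The ser-3 probe set was dim, at signals of 17 to 30.5, and was lower in the receptor mutant by -0.37 and -0.57. No probe set was assigned to ser-6. Which of these probe sets lie in the deleted parts is not given in the sources used here, and a probe set outside the deletion checks nothing about a label.

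In N2, a pair of lysozyme genes had the highest octopamine ratios and a probe set assigned to a serotonin receptor gene the lowest. The invertebrate-type lysozyme ilys-2 went from a signal of 10.1 to 113, a log2 ratio of 3.49. Its paralogue ilys-3 went from 25.2 to 187, a log2 ratio of 2.89. Further high ratios were those of the lipase-related gene lips-11 at 2.71, the asparagine synthetase asns-2 at 2.44, the aquaporin aqp-8 at 2.08, the linker histone his-24 at 2.00 and the lysozyme lys-10 at 1.89. The flavin-containing monooxygenase fmo-2 was higher by 1.81, and the uncharacterised genes Y110A2AL.4 and T02B11.4 by 2.48 and 2.45. The serotonin receptor ser-4 had the lowest ratio, -3.89, falling from a signal of 448 to 30.2 between these arrays. The gene ser-4 had no value without shared probe sets, whose suffix marks probes matching several transcripts. Its change may therefore not be that of ser-4 alone. Also lower were the neuropeptide receptor ckr-2 at -3.04, the downstream-of-DAF-16 gene dod-24 at -2.83, the T-box gene tbx-43 at -2.67, the aspartyl protease asp-14 at -2.46, the lectin clec-223 at -2.41 and the molting gene mlt-4 at -2.40. A probe set for the ribosomal RNA gene rrn-3.56 was lower by -3.50. Of 10251 genes, 123 were at least 2-fold higher and 149 at least 2-fold lower, so 45.2% of these were higher, against 57.5% with the values as deposited.

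**Figure D1:**
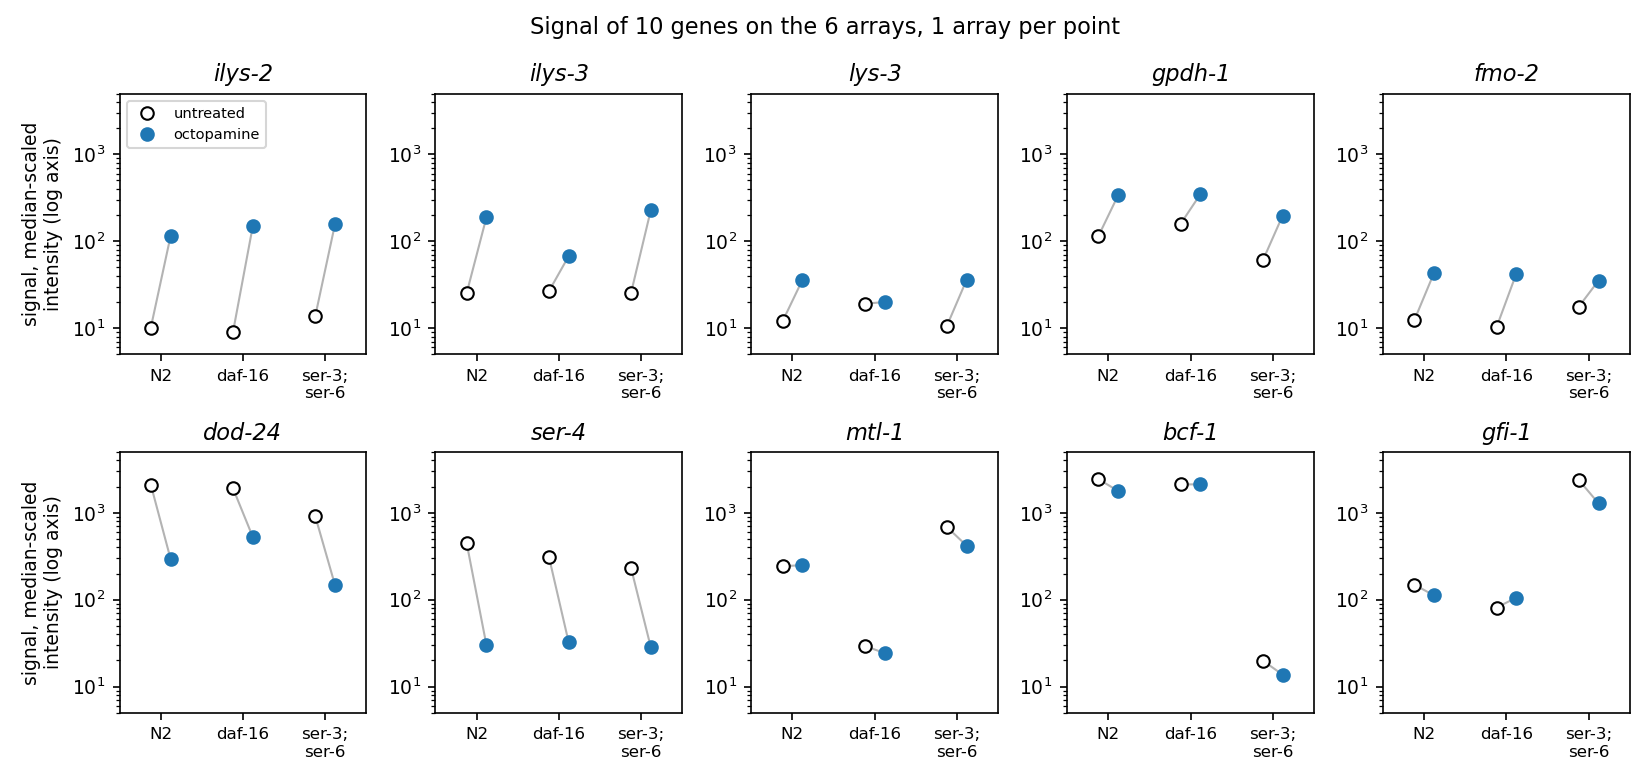
Signal of 10 genes on the 6 arrays on a log axis, without and with octopamine in each strain, with 1 point per array. The gene ilys-2 lies at 113 or more on each treated array, and bcf-1 is near 20 in the untreated receptor mutant against 2439 in untreated N2.

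Some of these genes were also at the ends of the range in the other strains. In daf-16 animals 79 genes were at least 2-fold higher and 117 lower, led upward by ilys-2 at 4.03, lys-10 at 2.52, the cathepsin B-like protease cpr-1 at 2.16, lips-11 at 2.14 and fmo-2 at 2.04. The low end held ser-4 at -3.26, ckr-2 at -2.34, tbx-43 at -2.31, and the glutathione S-transferase gst-38 at -2.16, which was -0.54 in N2 and -0.03 in the receptor mutant. In the receptor mutant 101 genes were at least 2-fold higher and 222 lower, with ilys-2 at 3.52, ilys-3 at 3.16 and the hatching protease hch-1 at 2.46 among the highest. The genes pud-4, at -3.04, and pud-3, at -2.83, the receptor gene ser-4, at -3.02, and the lysosomal lipase lipl-1, at -2.47, were among the lowest there. For lipl-1 the ratios in N2 and daf-16 were -0.26 and 0.13.

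Across strains the additive model called genes in both directions. By limma with Benjamini-Hochberg adjustment, ilys-2 rose by 3.68 ± 0.14 (log2, SE, adjusted p = 1.39e-05), higher in 3 of 3 strains. By the same limma test with Benjamini-Hochberg adjustment, ser-4 changed by -3.39 ± 0.16 (SE, adjusted p = 4.19e-05) and the uncharacterised gene C17C3.5 by -3.22 ± 0.09 (SE, adjusted p = 1.63e-06), each lower in 3 of 3 strains. The ser-4 result has the limit given above, as it had no value without shared probe sets. Among genes past the same threshold were lips-11 at 2.27 ± 0.15, his-24 at 1.76 ± 0.09, the small secreted protein nspe-7 at 2.12 ± 0.11, the collagen dpy-14 at 1.63 ± 0.10 and fmo-2 at 1.62 ± 0.19, all rising. Genes that fell included ckr-2 at -2.65 ± 0.15, dod-24 at -2.44 ± 0.16, tbx-43 at -2.40 ± 0.12, mlt-4 at -2.3 ± 0.11, asp-14 at -2.25 ± 0.12, the sperm kinase spe-6 at -1.94 ± 0.11 and the astacin protease nas-20 at -1.90 ± 0.11. In all 755 genes rose and 1511 fell, of which 72 and 119 did so by at least 2-fold. The balance depended on scaling: 33.3% of the called genes rose here, against 48.8% with the values as deposited and 52.6% after quantile normalization. Without the N2 pair of arrays 322 genes rose and 729 fell.

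**Figure D2:**
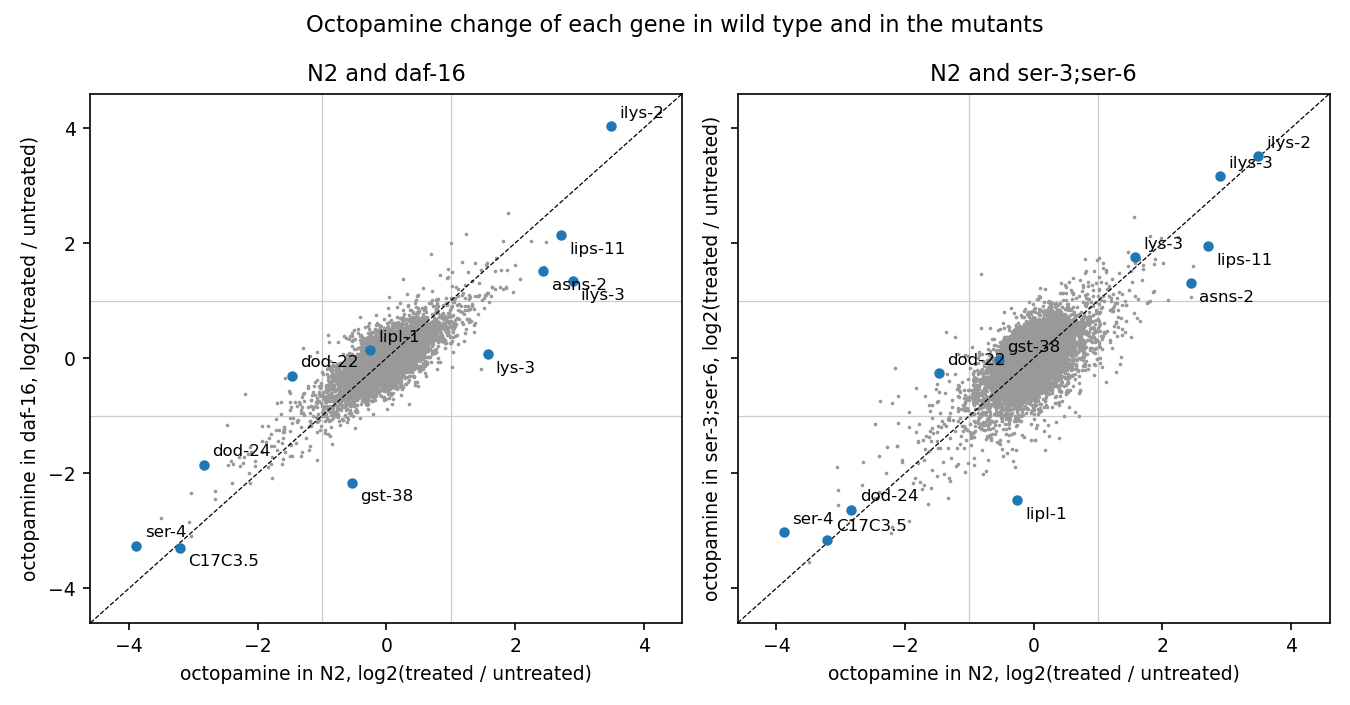
Octopamine log2 ratio of each gene in N2 (horizontal) against that in daf-16 and in the receptor mutant (vertical), 1 point per gene. The correlation across genes is 0.784 with daf-16 and 0.650 with the receptor mutant, and ilys-2 and ser-4 lie at the upper and lower ends in both.

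Genes of innate defence went both ways. Of 32 measured innate immune effectors 7 rose and 13 fell over all genes tested, and 8 rose and 15 fell adjusted over the list alone. Their median ratio was -0.36 in N2, -0.20 in daf-16 and -0.27 in the receptor mutant, below the central 95% of random lists in each. The rising members included the lysozymes ilys-2, ilys-3, lys-3 and lys-7, whereas the lysozymes lys-2 at -0.79 ± 0.09 and ilys-5 at -0.84 ± 0.12 fell. Also falling were the infection-response gene irg-4 at -1.23 ± 0.15, sysm-1 at -1.51 ± 0.13, C17H12.8 at -1.90 ± 0.13 and K08D8.5 at -2.29 ± 0.20. C-type lectins, carbohydrate-binding proteins, had medians of -0.13, -0.14 and -0.28 in the same order: of 69, 6 rose and 21 fell, or 6 and 23 adjusted over the list alone. All 5 vitellogenins, the yolk proteins, had negative ratios in each strain with median-subtracted values, but the median in daf-16, -0.19, became 0.00 after quantile normalization. Of them 0 rose and 4 fell, and 0 and 5 adjusted over the list alone, with vit-1 at -0.70 ± 0.07. The F-box proteins, substrate adaptors of ubiquitin ligases, stood apart upward in each strain at 0.13, 0.09 and 0.10, though in the receptor mutant not with the stricter filter (percentile 97.2). Of 134, 25 rose and 10 fell, and 32 and 14 adjusted over the list alone. The rise lay in the fbxb and fbxc genes, with 17 of 47 and 7 of 25 rising and 1 and 4 falling, while of 62 fbxa genes 1 rose and 5 fell, with medians of 0.02, -0.09 and -0.03.

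The median ratios of endoplasmic reticulum stress genes and of osmotic stress genes stood apart upward with octopamine in each strain, though not all members rose. Of 18 endoplasmic reticulum chaperones and unfolded-protein-response genes, 8 rose and 0 fell, with the same counts adjusted over the list alone, and medians were 0.27, 0.19 and 0.27 in N2, daf-16 and the receptor mutant. The chaperone hsp-3 rose by 0.68 ± 0.09, the disulphide isomerase pdi-2 by 0.65 ± 0.08 and calreticulin, crt-1, by 0.45 ± 0.06. Of 17 osmotic stress genes 7 rose and 2 fell, and 8 and 2 adjusted over the list alone. Their medians were 0.35, 0.10 and 0.15. The 7 that rose include lea-1, whose probe sets disagreed and whose ratio in daf-16 was -0.19. The glycerol-3-phosphate dehydrogenase gpdh-1, which makes glycerol under hypertonic conditions, rose by 1.47 ± 0.12, its paralogue gpdh-2 by 0.60 ± 0.09, and the inositol transporter hmit-1.1 by 0.60 ± 0.13. The antimicrobial-peptide-like genes of this list went both ways. The genes nlp-27 and nlp-33 fell, at -0.99 ± 0.11 and -0.90 ± 0.12, and nlp-28 and nlp-29 rose, at 0.45 ± 0.10 and 0.58 ± 0.09. Their relatives nlp-30 and nlp-31 did not pass. Of 14 heat shock genes, 0 rose and 1 fell, and 0 and 0 adjusted over the list alone. Of 8 mitochondrial chaperones 1 rose and 0 fell, and 2 and 1 adjusted over the list alone.

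Enzymes that remove reactive oxygen did not rise as a group. Of 21 antioxidant enzymes 2 rose and 7 fell, with the same counts adjusted over the list alone. The rising members were the peroxisomal catalase ctl-2 at 0.43 ± 0.12 and the thioredoxin reductase trxr-1 at 0.53 ± 0.11, and those that fell included the methionine sulphoxide reductase msra-1 at -0.76 ± 0.10 and the peroxiredoxin prdx-6 at -0.59 ± 0.13. The mitochondrial superoxide dismutase sod-3, a widely used DAF-16 reporter, had ratios of 0.27, 0.06 and 0.47. By limma with Benjamini-Hochberg adjustment its change of 0.27 ± 0.12 (SE, adjusted p = 0.139) did not pass, though it was higher in 3 of 3 strains. Among 19 SKN-1 and phase II detoxification genes 4 rose and 1 fell, and 6 and 2 adjusted over the list alone. The SKN-1 reporter gst-4 had ratios of 0.06 in N2, 0.41 in daf-16 and 1.02 in the receptor mutant, and its change of 0.50 ± 0.16 (SE, adjusted p = 0.0548 by limma with Benjamini-Hochberg adjustment), higher in 3 of 3 strains, did not pass. In the same order its untreated signals were 839, 469 and 316 and its treated signals 873, 623 and 641. The strains thus differed more without octopamine than with it.

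Class I DAF-16 targets, which are higher when insulin signalling is low, stood apart upward with octopamine in all 3 strains, the daf-16 strain included. Their medians were 0.21 in N2, 0.17 in daf-16 and 0.08 in the receptor mutant. Of 25, 8 rose and 4 fell, and 9 and 4 adjusted over the list alone: the glyoxylate-cycle enzyme icl-1 rose by 1.16 ± 0.08, the iron store ferritin ftn-1 by 1.15 ± 0.17 and dod-3 by 1.02 ± 0.15, while the metallothionein mtl-2 at -0.72 ± 0.16 and the saposin-like spp-1 at -0.78 ± 0.09 fell. The metallothionein mtl-1 had ratios of 0.05, -0.27 and -0.72, and its fitted change did not pass. Class II genes, lower when insulin signalling is low, had medians of -0.42, -0.26 and -0.32: of 12, 1 rose and 5 fell, and 1 and 8 adjusted over the list alone. The rising one was the insulin-like peptide ins-7 at 1.1 ± 0.16, and those that fell included dod-24 and dod-17. Of 20 insulin and FOXO pathway components 2 rose and 0 fell, and 1 and 0 adjusted over the list alone. The small heat shock protein gene hsp-12.6 lay below the filter at signals of 6.26 to 7.59.

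Genes known to be induced by fasting were mixed. Of 16, 5 rose and 0 fell, and 6 and 2 adjusted over the list alone. The rising members were icl-1, fmo-2, the acyl-CoA synthetase acs-2 at 1.08 ± 0.19, the carnitine palmitoyltransferase cpt-4 at 0.94 ± 0.17 and the lipase fil-1 at 0.82 ± 0.14. The lysosomal lipases lipl-1 and lipl-2 did not pass, and lipl-2 had ratios of -1.3, 0.18 and -0.95. The list's median was 0.02 in N2 and 0.07 in the receptor mutant, within the range of random lists, and 0.32 in daf-16, above it. Among 33 genes of fatty acid beta-oxidation 6 rose and 2 fell, with the same counts adjusted over the list alone. Among 21 desaturases, elongases and other lipogenic enzymes the counts were 2 and 4 both ways.

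Of 16 genes of monoamine signalling, 0 rose and 3 fell, and 1 and 5 adjusted over the list alone, and those that fell were ser-4, the dopamine receptor dop-4 at -0.45 ± 0.11 and cat-4, an enzyme of the cofactor of monoamine synthesis, at -0.42 ± 0.12. As above, ser-4 had no value without shared probe sets. The octopamine-synthesis genes did not pass: tbh-1 had ratios of -0.13, -0.06 and -0.61, and tdc-1 of -0.05, -0.34 and -0.10. Of 32 proteasome subunits 0 rose and 8 fell, and 0 and 9 adjusted over the list alone, with medians of -0.13, -0.19 and -0.24. These medians stood apart in daf-16 and the receptor mutant but not in N2. Body wall muscle markers had medians of 0.22, 0.12 and 0.07, the last standing apart only in part of the alternatives, with 4 of 30 rising and 0 falling and 2 and 0 adjusted over the list alone. Hypodermis and adult cuticle markers had medians of 0.18, 0.10 and 0.19, of which only the last stood apart under every alternative. Of 18, 7 rose and 3 fell, and 7 and 4 adjusted over the list alone. The largest rises were those of the hatching protease hch-1, at 1.88 ± 0.18, and sym-1, at 1.32 ± 0.14. Of the collagens in this list col-12 and col-93 rose, and col-19 and col-140 fell. Embryo markers had medians of 0.12, 0.02 and 0.28, which stood apart in N2 and the receptor mutant, but in neither with the stricter filter or with none, with 8 of 26 rising and 3 falling and 9 and 4 adjusted over the list alone, in samples of whole animals that can hold embryos. Intestine markers had medians of 0.09, 0.07 and -0.15, which stood apart in daf-16 and, except with the stricter filter, in N2, with 7 of 26 rising and 4 falling and 8 and 6 adjusted over the list alone. Larval cuticle markers stood apart in the receptor mutant at 0.22, with 5 of 24 rising and 0 falling by either adjustment, and oocyte and eggshell markers in N2 at -0.15, though not under every alternative, with 1 of 27 rising and 1 falling by either adjustment. Of 10 sperm markers 0 rose and 3 fell by either adjustment. The 23 msp genes, for major sperm proteins, had medians of 0.03, -0.41 and -0.18 in N2, daf-16 and the receptor mutant, and 0 rose and 1 fell. The list of major sperm proteins stood apart in daf-16 under every alternative. The 3'/5' signal ratio of the ubiquitin control transcript, a sign of RNA quality, was 5.32 to 5.48 on the untreated and 5.74 to 6.23 on the treated arrays, while that of actin ranged from 1.69 to 2.14 without such a split. For glyceraldehyde-3-phosphate dehydrogenase it went from 1.23 to 1.05 with octopamine in N2, from 1.24 to 1.03 in daf-16 and from 0.919 to 1.09 in the receptor mutant.

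**Figure D3:**
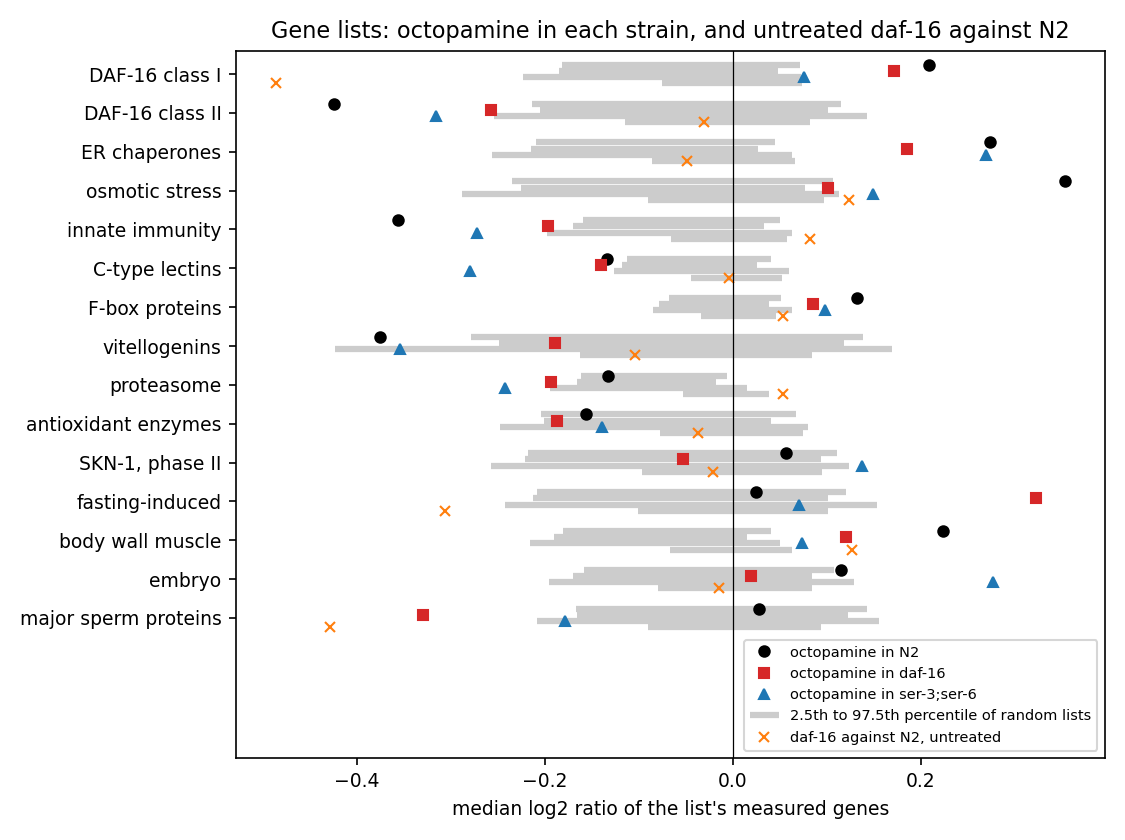
Median log2 ratio of 15 gene lists for octopamine in each strain and for untreated daf-16 against N2, with grey bars for the central 95% of random lists of the same size and expression. Class I DAF-16 targets lie above the bars for octopamine in each strain, at 0.21, 0.17 and 0.08, and below it for daf-16 against N2, at -0.49.

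The octopamine changes of the strains shared no array and were correlated across genes. Pearson's r was 0.784 between N2 and daf-16, 0.650 between N2 and the receptor mutant, and 0.637 between both mutants, with Spearman's rho of 0.685, 0.538 and 0.545. Past 2-fold in all 3 strains were 41 genes upward, against 0.00934 for independent lists, and 69 downward, against 0.0368. They included the genes ilys-2, nspe-7, lips-11, his-24 and dpy-14 upward and ser-4, C17C3.5, ckr-2, tbx-43 and mlt-4 downward. No gene was past 2-fold in opposite directions in a pair of strains.

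The dependence of the change on DAF-16 was read from the 272 genes past 2-fold in N2. Of these, 228 (83.8%, 95% Wilson interval 79.0 to 87.7) kept at least 50% of the N2 log2 change in daf-16. In reverse, of 196 genes past 2-fold in daf-16, 185 (94.4%, 90.2 to 96.8) kept at least 50% in N2. Genes that differed most were the lysozyme lys-3, at 1.57 in N2, 0.06 in daf-16 and 1.76 in the receptor mutant, and ilys-3, at 2.89, 1.34 and 3.16. The lysosomal carboxypeptidase gene pcp-2 had ratios of -2.2, -0.62 and -0.79, mbug-1 of -1.58, -0.34 and -1.94, dod-22 of -1.47, -0.30 and -0.26, and the peroxisomal transporter gene pmp-5 of -1.18, 0.04 and -0.46. The desiccation protein gene lea-1 was at 1.47, -0.19 and 1.84, but its 6 probe sets disagreed, and without shared probe sets its N2 ratio was -0.17. Whether any of these genes differed between strains was not tested.

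The receptor mutant was read in the same way. Of the 272 genes past 2-fold in N2, 203 (74.6%, 69.1 to 79.4) kept at least 50% of the change in the receptor mutant, and of 323 genes past 2-fold in the receptor mutant, 225 (69.7%, 64.4 to 74.4) kept it in N2. Of the 272 genes, 11 had the opposite sign there. Examples in N2, daf-16 and the receptor mutant were the saposin-like spp-12, at 1.27, 1.5 and -0.23, and mnp-1, at 1.06, 0.62 and -0.15. Others were the acyltransferase-like oac-32, at -1.22, -0.85 and 0.37, and the homeobox gene ttx-1, at -1.37, -0.76 and 0.46. The neuropeptide gene nlp-35 had ratios of 1.36, 0.58 and 0.02, and ugt-21 of 1.12, 0.25 and -0.42. The shares for the mutants were not tested against each other. These genes were picked for their N2 ratio, which by itself favours larger values in N2, and the differences were not tested.

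The daf-16 strain differed from N2 in few genes, with DAF-16 targets among the lowest. Without and with octopamine mtl-1 was lower by -3.04 and -3.36, ftn-1 by -1.90 and -1.75, and the uncharacterised genes F15B9.6 by -1.99 and -1.62 and T12D8.5 by -1.37 and -1.63. The fatty acid elongase elo-6 was lower by -1.57 and -0.87. Higher were F42A10.7, at 1.67 and 1.65, and the infection-response genes irg-5, at 1.08 and 1.45, and irg-4, at 0.97 and 1.26. The gene gst-38 was higher by 2.09 without and 0.47 with octopamine, the former from its high signal on the untreated daf-16 array. By limma with Benjamini-Hochberg adjustment, the mtl-1 difference was -3.20 ± 0.18 (SE, adjusted p = 0.000602), and the ftn-1 difference was -1.82 ± 0.21 (SE, adjusted p = 0.0142), each lower in both treatments. In all 4 genes were called higher and 21 lower over both treatments, and only 2 and 4 when the model had no trend. Past 2-fold were 5 higher and 35 lower genes without octopamine and 8 and 32 with it.

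Class I targets were lower in daf-16 as a group, with medians of -0.49 without and -0.61 with octopamine, at percentile 0 among random lists in both. Of 25, 0 rose and 5 fell in the additive model, and 0 and 14 adjusted over the list alone. Those that fell were mtl-1, ftn-1, icl-1, the lysozyme lys-7 and the non-coding RNA tts-1. Class II genes stood apart only with octopamine, at a median of 0.25, while without it the median was -0.03 and its sign changed with scaling. Of 12, 0 passed over all genes, and 2 rose and 0 fell adjusted over the list alone. Fasting-induced genes had medians of -0.31 and -0.13, the latter within the random range after quantile normalization, with 0 rising and 1 falling, and 0 and 3 adjusted over the list alone. Major sperm proteins, abundant sperm cytoskeleton proteins, were lower at -0.43 and -0.88. Of 25, 2 fell over all genes and 19 adjusted over the list alone. The list was not read without shared probe sets, so its members may not be separate measurements. Collagens, body wall muscle markers and pharynx markers stood apart upward without octopamine, at 0.10, 0.13 and 0.13, but not with it, at -0.04, 0.01 and 0.05. None of their genes passed over all genes or over the list alone. Hypodermis and adult cuticle markers stood apart upward without octopamine, at 0.09, but not under every alternative.

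The receptor mutant differed from N2 most in bcf-1, whose signal was 2439 in untreated N2 and 19.9 in the untreated mutant. By limma with Benjamini-Hochberg adjustment the difference was -6.98 ± 0.14 (log2, SE, adjusted p = 1.42e-07), lower in both treatments. Its neighbour in the gene order, gfi-1, was higher by 4.00 and 3.52 without and with octopamine. Another adjacent pair, lrk-1, a homologue of the Parkinson's kinase LRRK, and mop-25.3, was lower by -1.98 and -2.42 and by -3.04 and -2.36. Also lower were the transporter haf-6 at -1.95 and -1.89, the tryptophan-catabolism enzyme haao-1 at -1.62 and -1.58, fip-2 at -2.02 and -2.49, and clec-190 at -2.34 and -2.0. The ciliary gene dyf-3 was higher by 1.55 and 1.98 and mtl-1 by 1.5 and 0.73. Over both treatments 41 genes were called higher and 228 lower, which was 15.2% higher, against 27.8% with the values as deposited and 37.2% after quantile normalization. The model without a trend called 11 and 76, and 91 were lower after quantile normalization. Past 2-fold were 22 higher and 69 lower genes without octopamine (24.2% higher, against 38.8% as deposited) and 15 and 133 with it (10.1%, against 20.9% after quantile normalization).

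Body wall muscle markers, collagens, transthyretin-related proteins and major sperm proteins stood apart downward in the receptor mutant without and with octopamine, while the lists of hypodermis and adult cuticle markers and of sperm markers did not stand apart. Without octopamine, intestine markers stood apart upward, at 0.11, and oocyte and eggshell markers and germline markers downward, at -0.19 and -0.17, the germline markers not under every alternative. None of these lists stood apart with octopamine, and 0 of their genes passed. Embryo markers stood apart upward at 0.10 without and 0.22 with octopamine, the latter not under every alternative, with 2 of 26 rising and 0 falling by either adjustment. Larval cuticle markers stood apart upward only with octopamine, at 0.11, and not under every alternative. Body wall muscle markers had medians of -0.29 without and -0.58 with octopamine, with 10 of 30 falling and 0 rising and 18 falling adjusted over the list alone. The troponin gene tni-3 had ratios of -0.79 and -1.37. Collagens had medians of -0.22 and -0.19, with 12 of 94 falling and 0 rising, and 24 falling and 1 rising adjusted over the list alone. Transthyretin-related proteins were at -0.25 and -0.35, with 3 of 30 falling and 10 adjusted over the list alone. Major sperm proteins were at -0.48 and -0.68, with 6 of 25 falling and 21 adjusted over the list alone. As above, these may not be separate measurements. Class I targets were slightly higher, at 0.14 and 0.12, with mtl-1 the 1 gene rising over all genes and 0 falling, and 1 and 1 adjusted over the list alone. Endoplasmic reticulum chaperones stood apart upward without and with octopamine. Without octopamine F-box proteins stood apart upward and class II genes downward, each under every alternative. The untreated medians were 0.37 for fbxb, 0.19 for fbxc and -0.01 for fbxa genes.

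The octopamine change was also set against the strain differences across genes. With untreated N2 as the shared array, the change in N2 correlated with the daf-16 difference at 0.293, against 0.496 simulated without effects, with a covariance of 0.0258 against 0.0247. With treated N2 shared the correlation was -0.252 against -0.5, and the covariance -0.0232 against -0.025. With no shared array, the change in the receptor mutant correlated with the daf-16 difference at 0.136 without and -0.0176 with octopamine. For the receptor mutant's difference from untreated N2, the correlation with the change in N2 was 0.499, against 0.498 simulated, with a covariance of 0.0613 against 0.0248. With treated N2 shared, that correlation was 0.0805 against -0.498, and the covariance 0.0114 against -0.0248. With no shared array, the change in daf-16 correlated with the receptor mutant's difference at 0.392 without and 0.217 with octopamine.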

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

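The first 3 results are octopamine ratios that pointed in opposite directions in a pair of strains, each strain being 1 pair of arrays, and these differences were not tested. The antibacterial peptide gene abf-2 was higher with octopamine in the receptor mutant, at a log2 ratio of 1.45, and lower in daf-16, at -0.83, a difference of 2.28. The neuropeptide gene flp-3 was lower in the receptor mutant, at -1.01, and higher in N2, at 0.71, a difference of -1.71, with a treated signal in the receptor mutant below the filter, so its size is uncertain. The collagens, cuticle proteins, had a median of 0.06 in the receptor mutant and -0.14 in daf-16, a difference of 0.20.

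Control probe sets outside the gene comparisons also moved with octopamine in each of the 3 strains. Those named for catalase were higher by a mean log2 ratio of 0.59 (0.38 to 0.92 over strains) at the 3' end, 0.64 (0.52 to 0.86) in the middle and 0.61 (0.36 to 0.94) at the 5' end. The 5' probe set named for glyceraldehyde-3-phosphate dehydrogenase was higher by 0.45 (0.36 to 0.51).

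Among 445 probe sets assigned to several genes, which the gene comparisons did not use, 9 were past 2-fold the same way in all 3 strains, 2 higher and 7 lower. The lowest was a probe set for copies of the ribosomal RNA gene rrn-4 at -5.61 in N2, -4.84 in daf-16 and -5.11 in the receptor mutant. A probe set for rrn-3.1 and rrn-3.56 was at -3.49, -3.05 and -3.63, and one for the histone genes his-66, his-58 and his-48 at -1.55, -1.56 and -1.19. The higher ones were for pgph-1, pgph-2 and pgph-3, at 1.60, 1.42 and 1.08, and for spig-4 and spig-5, at 1.31, 1.48 and 1.3. Whether the ribosomal RNA and histone changes came from the animals or from RNA preparation and labelling was not tested.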

How the results depend on the processing

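The additive model compares octopamine within each strain's pair of arrays, and each mutant with N2 over both treatments; comparisons between a pair of arrays have no test. Of the counts, correlations and shares, 289 stayed within the limits set for them under the alternatives run and 48 moved. Of the gene-list percentiles 1968 kept their side, 49 came to stand apart, 73 no longer did and 3 reversed. Most of these percentiles did not stand apart to begin with: of 117 pairs of a list and a comparison that did, 68 did so under every alternative. Of the named-gene ratios 870 kept theirs, 2 were stronger, 3 weaker and 2 reversed. A change of filter leaves a gene's ratio as it was. The 123 unchanged ratios with no filter and the 84 with the stricter filter therefore say nothing about robustness. Some named genes had no value under an alternative and were not checked by it: without shared probe sets these included ser-4, bcf-1, gfi-1, lrk-1, asns-2, asp-14, mlt-4, nspe-7, ftn-1 and dod-24, and with the stricter filter ilys-2, lys-10, ckr-2, fmo-2, nspe-7 and lrk-1. Values as deposited and the floor, which lies under the filter, cannot move percentiles, so they say nothing about them. Signals near background limit the rest, as over 50% of probe sets had a signal under 30 on each array. Except where fewer genes or another threshold decide it by construction, the cause was not tested.

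Additive model: for octopamine across the 3 strains the genes that rose numbered 322 to 890 and those that fell 729 to 1765 when a strain's pair was left out, the lowest being without the N2 pair; no strain term gave 180 and 333. Without trend, daf-16 against N2 over both treatments gave 2 and 4 genes and ser-3;ser-6 against N2 over both treatments 11 and 76. Quantile normalization gave 877 falling with octopamine and 91 lower in ser-3;ser-6 against N2 over both treatments, and values as deposited 1004 and 122. Without shared probe sets, chosen after seeing the data, 482 rose with octopamine.

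Counts at a 1.5-fold threshold (higher and lower) were 451 and 566 for octopamine in N2, 295 and 480 for octopamine in daf-16, 460 and 870 for octopamine in ser-3;ser-6, 119 and 226 for octopamine in all 3 strains, 49 and 155 for daf-16 against N2 without octopamine, 67 and 137 for daf-16 against N2 with octopamine, 190 and 358 for ser-3;ser-6 against N2 without octopamine, and 231 and 689 for ser-3;ser-6 against N2 with octopamine. The shares keeping at least 50% of the change were then 72.0% from N2 to daf-16, 65.3% from N2 to ser-3;ser-6, 84.8% from daf-16 to N2, 72.0% from daf-16 to ser-3;ser-6, 53.8% from ser-3;ser-6 to N2 and 52.2% from ser-3;ser-6 to daf-16.

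With the stricter filter on dim genes, the lower genes numbered 83 for octopamine in N2, 76 for octopamine in daf-16, 45 for octopamine in all 3 strains, 22 for daf-16 against N2 without octopamine and 39 for ser-3;ser-6 against N2 without octopamine, 7 were higher for ser-3;ser-6 against N2 with octopamine, and 89.4% of genes kept the change from N2 to daf-16. Quantile normalization gave 28 higher genes for ser-3;ser-6 against N2 with octopamine, values as deposited 9 higher for daf-16 against N2 without octopamine, and no filter on dim genes a correlation of the octopamine change, N2 with daf-16, of 0.699. Without shared probe sets, 64 genes were higher for octopamine in ser-3;ser-6, 18 lower for daf-16 against N2 with octopamine and 8 higher for ser-3;ser-6 against N2 with octopamine, and lea-1 reversed to -0.17 for octopamine in N2 and 0.19 for daf-16 against N2 with octopamine.

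The percentiles that reversed were those of list innate immune effectors, ser-3;ser-6 against N2 with octopamine, at 92.8 with no filter, and, with the stricter filter, list fasting-induced genes, ser-3;ser-6 against N2 with octopamine, at 55.7, and list C-type lectins, ser-3;ser-6 against N2 without octopamine, at 73.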

Other observations

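The tests of splits, hybridisation controls, osmotic genes, neighbouring genes and receptor genotype were chosen only after the results were seen, as were the gene families and the removal of shared probe sets. Families of genes with a common name were ranked by the percentile of their mean octopamine change. Those named here were picked from the ends of that ranking. Some of them moved in the same direction with octopamine, given here in the order N2, daf-16 and the receptor mutant. The fbxb genes, which are part of the F-box list, had medians of 0.41, 0.25 and 0.24, with 17 of 47 rising and 1 falling in the additive model. Aspartyl proteases (asp) had medians of -0.45, -0.47 and -0.41, with 1 of 10 rising and 6 falling, and the small secreted nspg proteins medians of -0.40, -0.37 and -0.44, with 0 of 9 rising and 6 falling. Histone genes (his) were at -0.43, -0.35 and -0.18, with 3 of 24 rising and 12 falling. In the receptor mutant the median lay within the random range (percentile 14.9) and was -0.08 after quantile normalization. The linker histone his-24 was among the genes that rose most. None of these directions changed with quantile normalization or with the values as deposited. The skr genes, which link F-box proteins to ubiquitin ligases, were at 0.51 in N2 and 0.25 in daf-16 but at -0.05 in the receptor mutant, where quantile normalization turned the sign to 0.06. Against N2 their median in the receptor mutant was already 0.20 without octopamine, and 0.02 with it. The smaller ratio there thus goes with a higher untreated signal, and the difference between strains was not tested.

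The octopamine change shared by the 3 strains was weighed against technical explanations. Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many genes as the real split. That 1 was the real split itself, with 2266 genes against 0 for the highest other. The other splits mix treated and untreated arrays, so a shared octopamine change enters their error and lowers their counts. As 10 splits are also too few for a share under 0.05, this test cannot decide about chance. A scaling difference between arrays is argued against by the correlation between strains, which was at least 0.629 after quantile normalization, and cross-hybridising probe sets by the share of genes called without them, 0.96 of that with them. Other technical explanations stay open: the treated arrays may have been processed apart, as the hybridisation controls were lower there by a mean of -0.16 (-0.06, -0.18 and -0.25 by strain), although as deposited, a check added after the result was seen, they were at 0.03, -0.14 and -0.20, and octopamine plates may be hypertonic, as the osmotic stress list stood apart upward in 3 of 3 strains. An effect of octopamine itself, the treatment the design names, also stays open. The lower signals of ribosomal RNA and histone probe sets on the treated arrays were not weighed in these tests.

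Differences between the receptor mutant and N2 past 2-fold on both pairs of arrays comprised 31 genes. Variants close to the ser-3 and ser-6 deletions are argued against as the source of most of these genes. Of the 31, 1 lay within 200 genes of either locus, against a median of 1 and a 95th percentile of 3 in random lists. The count cannot exclude such variants for a few genes, or linked variants farther away. Strain variants that span neighbouring genes are a candidate explanation for part of the 31 genes. Of these, 8, or 25.8% (95% Wilson interval 13.7 to 43.3), had a neighbour in the list, against a random median of 0 and 95th percentile of 2 genes. For genes past 2-fold with octopamine in all 3 strains, where no strain variant enters, the share was 12.7% (7.7 to 20.2). The intervals overlap, but neighbours are counted together and are not independent, so the overlap decides nothing. Of the genes changed by octopamine 14 had a neighbour, against a random median of 2 and 95th percentile of 6. Neighbours are therefore not particular to the strain difference, and clusters of related genes stay open as a source. The loss of the receptors remains an untested explanation for the rest.

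Untreated receptor-mutant animals lay along the octopamine change. An untreated N2 array apart from the others is argued against, since the change in N2 still correlated at 0.275 across genes with the difference of the receptor mutant from daf-16, which shares no array with it. A common intensity-dependent scaling error is argued against by a correlation of 0.372 after quantile normalization between the change in daf-16 and the receptor mutant's difference from N2. Whether this may come from the receptor strain's genotype cannot be told apart from its array, as 1 array stands for that group: its correlation exceeded that of the daf-16 difference by 0.256. That untreated array also differed in 3'/5' signal ratios. For glyceraldehyde-3-phosphate dehydrogenase it had 0.919, against 1.23 and 1.24 in untreated N2 and daf-16 and 1.03 to 1.09 on the treated arrays. For actin it had 1.69 against 2.03 and 2.14, and for ubiquitin 5.48 against 5.32 and 5.37. Whether RNA quality explains the pattern was not tested.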
